A study of Schima superba and Cryptocarya concinna with 24 samples.

How the data were processed

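RNA came from flash-frozen leaves of tree seedlings, extracted with a column kit from Sangon for S. superba and a kit from Magen for C. concinna, and libraries followed standard Illumina protocols, per the labels. Kits and tables differ between the species, so each species was analysed on its own. The authors' tables gave FPKM per library and unigene, fragments scaled to unigene length and to the mapped fragments of the library. The tool named for them was RSEM 1.2.12, per the submitters' processing notes, and each library had a column of its own, per the file headers. The assembler, aligner and read filters were not given in the sources used here. Since FPKM are not counts, no count model was used. Each table also gave a best protein database hit per unigene, for 32354 of 57053 unigenes (56.7%) in S. superba and 36136 of 60814 (59.4%) in C. concinna. Hits with a usable description, not uncharacterised, hypothetical, unknown or predicted alone, numbered 17375 and 19622. No reference genome was used, so unigenes carry no coordinates, and gene names are those of the best hits.

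Samples were grouped by leaf age (young, mature) and light (full, low) as the labels give them, with 3 replicates per group. Depth was compared between libraries from the steps between FPKM values of 0.25 to 1.5, where a unigene's values are multiples of what 1 fragment is worth. Absolute depth stayed unknown, so no counting interval was computed and the error of values near 0 could not be given. Exact zeros were read as listed at 0, and values fitted against them are no bound. Replicates were compared by the SD of log2 ratios over unigenes with a pair mean FPKM of at least 50. SDs in S. superba were 0.765 to 1.37, but 0.368 for young low light replicates 2 and 3 (Pearson r 0.959 across unigenes). Both were kept, as values differed, but their independence is unknown, and light calls in young leaves were fewest without replicate 2.

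Unigenes with FPKM of at least 1 in at least 3 of the 12 libraries of a species were tested (50970 and 53005). Values entered as log2(FPKM + 1) into limma 3.58.1 in R 4.3.3, with a mean per group, all 4 groups sharing the spread, empirical Bayes moderation with trend, two-sided tests and Benjamini-Hochberg adjustment over the unigenes tested. Calls were made at an adjusted p under 0.05. Light was full minus low, age young minus mature, and light by age the light effect in young minus that in mature leaves, so 5 comparisons were made per species. Overlaps of calls were set beside those of independent lists. Breadth and dominance were compared by two-sided exact permutation tests. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The groups, tests, gene lists, rule for named genes and first set of other settings were fixed before the data were examined.

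Gene lists were taken by word patterns on the descriptions. They covered flavonoid and anthocyanin synthesis, phenylpropanoid and lignin synthesis, light-harvesting antenna, photosystem and electron transport, photoprotection, Calvin cycle and Rubisco, chlorophyll synthesis, carotenoid synthesis and antioxidant enzymes. Further lists were light receptors and signalling, heat shock and chaperones, cell wall expansion, cell cycle and DNA replication, ribosomal proteins, cuticle and wax, starch and sucrose, leaf senescence, and MYB and bHLH factors. Auxin, abscisic acid and drought, jasmonate, pathogenesis-related and terpenoid lists completed the set, with markers of vascular tissue, of trichome, epidermis and guard cell, of organelle-encoded and ribosomal RNA, and of other organisms. The last matched only a vitellogenin (Unigene21311) in C. concinna and was not tested. The other 26 lists were tested with camera of limma at a preset correlation of 0.01 and with an estimated one, adjusted over lists and comparisons within a species. With all libraries no camera call held at an estimated correlation (lowest adjusted p 0.0831). Without mature low light replicate 2 of C. concinna, cuticle and wax gave 0.0157 and 0.0233 for age in low and full light. Patterns take in look-alikes, so a list is a set of descriptions, not a curated pathway.

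Named genes followed a rule. Per light comparison these were the 10 largest positive and 10 largest negative log2 changes (5 and 5 for age and light by age) among called unigenes with a usable description, groups that did not overlap and mean FPKM of at least 10 in the higher group. From each list came the called member with the largest absolute change and mean FPKM of at least 5. For light by age, with 4 groups, the condition on overlap was not applied. The rule gave 273 pairs of unigene and comparison, of which the text uses 110. Other settings fixed at the start were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, the replicate number as a block, limma without trend, only the 2 groups compared, a 2-fold minimum, other thresholds of breadth and dominance, and each library left out. Summing the contigs of a cluster, leaving out the low light libraries numbered 1 of S. superba or, for lists, mature low light replicate 2 of C. concinna, removing its most abundant unigene, matching short symbols as whole words, and rescaling for the lists were added after seeing the data, as was a camera test over Gene Ontology terms of 15 to 500 members.

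Tests were tried on simulated, uncorrelated values for all unigenes tested, from their means and spreads (seed 11). Of these, 200 of mean log2 over 2 were changed by 1, 2 or 4 (log2). For light in young leaves 5.97%, 58.2% and 93.9% of them were called in S. superba and 1.49%, 64.2% and 92.4% in C. concinna. For light by age the shares were 0%, 31.3% and 74.2%, and 1.49%, 25.4% and 78.8%. Over all comparisons 1.39% to 8.47% of calls were unchanged unigenes. Per comparison camera found a set of 40 moved by 1, and an unmoved set gave p of 0.0537 or more. Such uncorrelated sets cannot calibrate it. Counts were set against splits of the libraries, all 10 for 3 against 3 and 100 drawn of 200 for light by age (seed 7).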

Results

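Leaf RNA was sequenced from seedlings of 2 subtropical forest trees, Schima superba and Cryptocarya concinna, grown in full sunlight or under black nylon net at 30% of it. Young and mature leaves sampled in each light gave 4 groups of 3 libraries per species, 24 in all. The deposited tables held FPKM for 57053 assembled transcripts (unigenes) of S. superba and 60814 of C. concinna. Summed FPKM per library ran from 769590 to 977280. Total read numbers were not given in the sources used here, but the steps between low values put the depth of the other libraries at 0.953 to 1.02 times that of the first library in S. superba and at 0.914 to 1.04 times in C. concinna. All values below are FPKM as mean ± SD with n = 3 unless stated otherwise, log2 fold changes are on the log2(FPKM + 1) scale, and adjusted p-values are from limma's moderated test. The labels do not state that the 3 replicates of a group came from separate plants, so p-values measure only the spread between these samples, which can be technical.

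Leaf age separated the libraries of both species along the first principal component, which held 57.2% of the variance in S. superba and 54.6% in C. concinna. Mature leaves concentrated their transcripts in fewer abundant unigenes. The 100 most abundant took 15.7 ± 3.33% of summed FPKM in young and 29.6 ± 2.39% in mature S. superba (n = 6 each, two-sided exact permutation p = 0.00216), and 17.8 ± 2.8% against 36.4 ± 7.98% in C. concinna (p = 0.00216, exact permutation). A metallothionein (Unigene13627), a small cysteine-rich metal-binding protein, reached 25405, 22922 and 25872 FPKM in mature S. superba in full light, against 151, 307 and 146 in young leaves. A repetitive proline-rich cell wall protein (CL2130.Contig2) reached 61381, 201070 and 301100 FPKM in mature C. concinna in full light and 76594, 88178 and 63181 in low light. Unigenes with an FPKM of at least 1 numbered 43403 ± 483 in young and 36365 ± 2170.2 in mature S. superba (p = 0.00216, the smallest that 6 against 6 can give in an exact permutation test). In C. concinna they numbered 38208 ± 4539 and 40422 ± 3068 (exact permutation p = 0.336). Within an age, 3 libraries against 3 cannot give a p below 0.1, which young C. concinna reached with 41966 ± 1792 such unigenes in full and 34449 ± 2432 in low light.

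**Figure D1:**
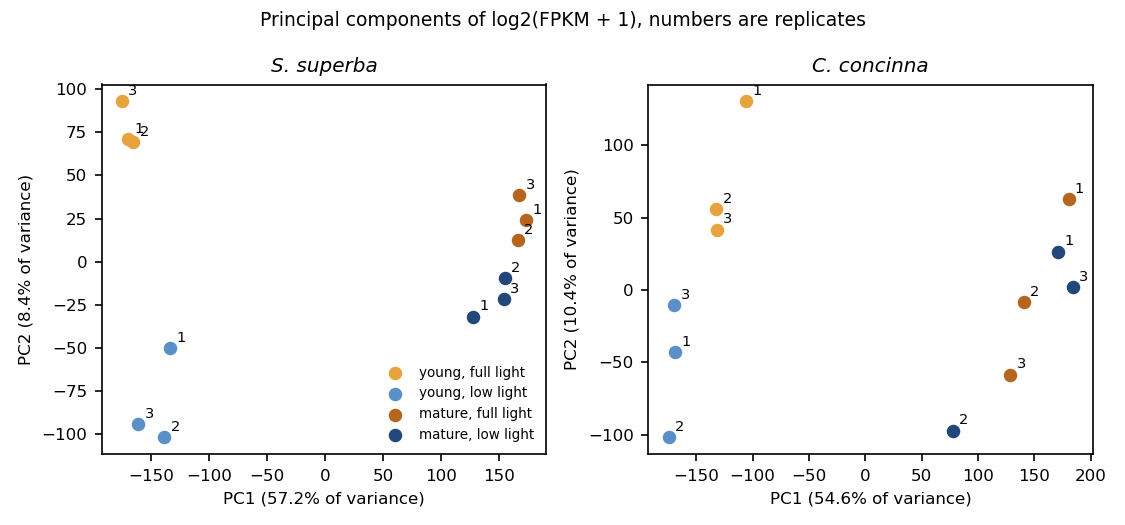
Principal components 1 (x axis) and 2 (y axis) of log2(FPKM + 1) per library, with the share of variance in percent on each axis and 1 point per library, for S. superba and C. concinna. Young and mature libraries of each species lie at opposite ends of component 1 (57.2% and 54.6%), and C. concinna mature low light replicate 2 lies closest of the mature libraries to the young ones.

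**Figure D2:**
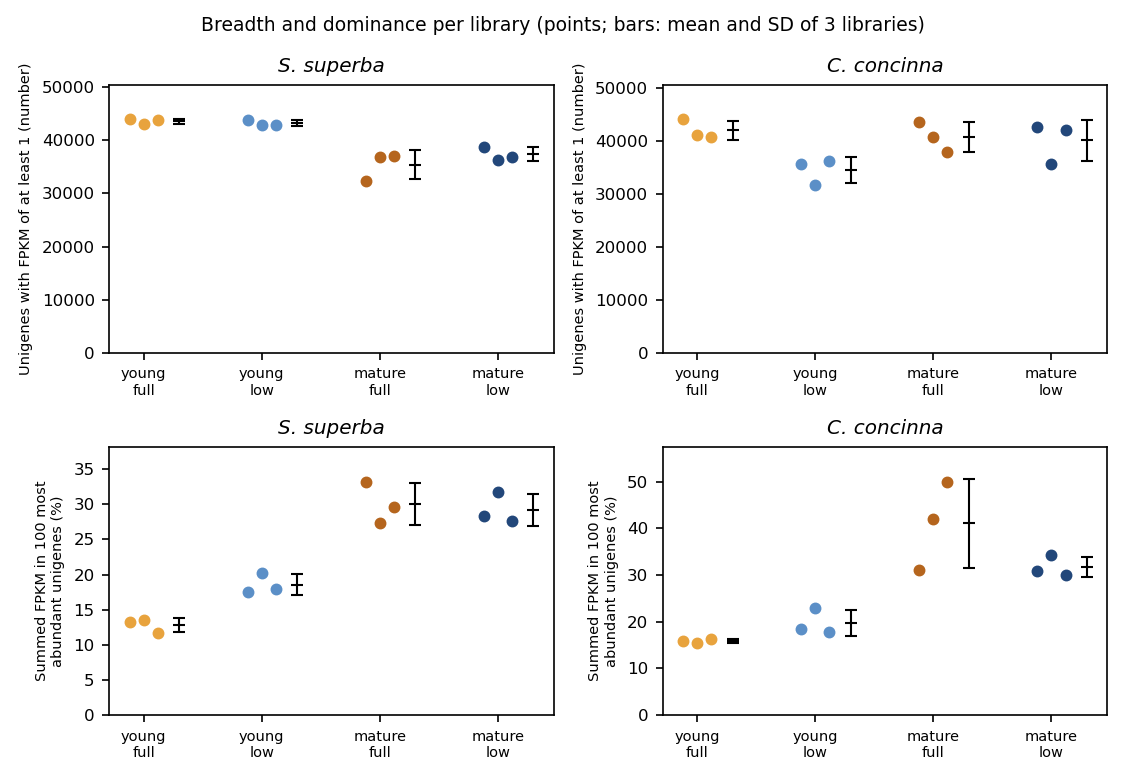
Number of unigenes with an FPKM of at least 1 and percent of summed FPKM in the 100 most abundant unigenes, per group, with points for libraries and bars for mean ± SD (n = 3). The 100 most abundant unigenes took a larger share in mature than in young leaves of both species, and the number of unigenes was lower in mature leaves of S. superba, at 36365 ± 2170.2 against 43403 ± 483.

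The light comparison asked how leaves grown in full sunlight and under shade differ. In young leaves of S. superba, the called antenna and photosystem unigenes were lower in full light and all but 1 of the called cell cycle unigenes higher. A chlorophyll a-b binding protein (CL4449.Contig1), which carries antenna pigment, stood at 386 ± 103 FPKM in full and 1901 ± 93.7 in low light (log2 fold change -2.33, SE 0.35, adjusted p = 0.00713). The photosystem II 5 kD family protein (Unigene35556) fell from 239.7 ± 72.6 in low to 3.03 ± 1.89 in full light (adjusted p = 0.00854). Among 35 antenna unigenes tested, 0 were higher and 14 lower (0 and 25 adjusted over the list alone, camera adjusted p = 2.20e-17, adjusted p = 0.225 with an estimated correlation), and the list median was -1.25. Among 40 photosystem and electron transport unigenes tested, 0 were higher and 19 lower (list-alone 0 and 21, camera adjusted p = 1.15e-15, estimated-correlation adjusted p = 0.173). For the Calvin cycle and Rubisco list the counts were 2 higher and 4 lower of 37 (list-alone 2 and 9, camera adjusted p = 1.05e-05, estimated-correlation adjusted p = 0.353). Among 183 cell cycle and DNA replication unigenes tested, 28 were higher and 1 lower (list-alone 57 and 5, camera adjusted p = 6.99e-08, estimated-correlation adjusted p = 0.353), and 17 and 0 after median-ratio rescaling. Without the low light libraries numbered 1 the counts were 0 and 4 for antenna, 0 and 10 for photosystems and 19 and 0 for the cell cycle.

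Single genes of other functions changed as well. Higher in full light were a gibberellin-regulated protein (Unigene1454), at 462 ± 224 against 9.92 ± 7.44 FPKM (log2 fold change 5.66, SE 0.59, adjusted p = 0.00189). An S-adenosylmethionine decarboxylase (Unigene9115), an enzyme of polyamine synthesis, stood at 176 ± 46.6 against 9.22 ± 1.43 (adjusted p = 7.41e-05). A flavanone 3-dioxygenase (CL2809.Contig2), an enzyme of flavonoid synthesis, was also higher, at 32.6 ± 9.04 against 1.5 ± 1.36 (adjusted p = 0.0027). Inositol oxygenase 1 (Unigene8528) rose to 52.1 ± 18.3 from 2.34 ± 0.665, and 3-ketoacyl-CoA synthase 17 (Unigene29370), of the family that elongates very long fatty acids, to 24.1 ± 12 from 0.030 ± 0.052. Lower in full light were a class II small heat shock protein (CL4946.Contig2), a chaperone, at 26.2 ± 17.5 against 710.2 ± 262 (log2 fold change -4.84, SE 0.55, adjusted p = 0.00278). So were the BAG family molecular chaperone regulator 6 (CL1982.Contig4), at 2.26 ± 1.79 against 149 ± 125, and a cinnamoyl-CoA reductase (Unigene13533), of the lignin pathway, at 2.61 ± 3.67 against 52.8 ± 7.68. Contigs named CL belong to clusters of similar sequences that can share reads, so they are uncertain. A gigantea contig (CL1709.Contig1), of the circadian clock, stood at 82.8 ± 10.3 against 5.33 ± 3.99 (log2 fold change 3.91), yet the sum of its cluster gave -0.066 (adjusted p = 0.885). A dehydrin contig (CL5121.Contig1), of a protein family tied to water deficit, gave 4.21 alone and 0.81 summed (adjusted p = 0.404).

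In all, limma called 2717 of 50970 unigenes tested, 1537 higher and 1180 lower in full light, at an adjusted p under 0.05. In 32.1% of unigenes the groups did not overlap, where chance gives 10%. The direction of the split followed the scaling: 56.6% of the changed unigenes were higher as deposited, 44.4% after median-ratio rescaling and 48.2% after quantile normalization. Leaving out young full light replicate 1, 2 or 3 or young low light replicate 2 or 3 gave 481 to 1540 calls, lowest without young low light replicate 2. A pseudocount of 0.1 gave 1303, and leaving out the low light libraries numbered 1 gave 1827.

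**Figure D3:**
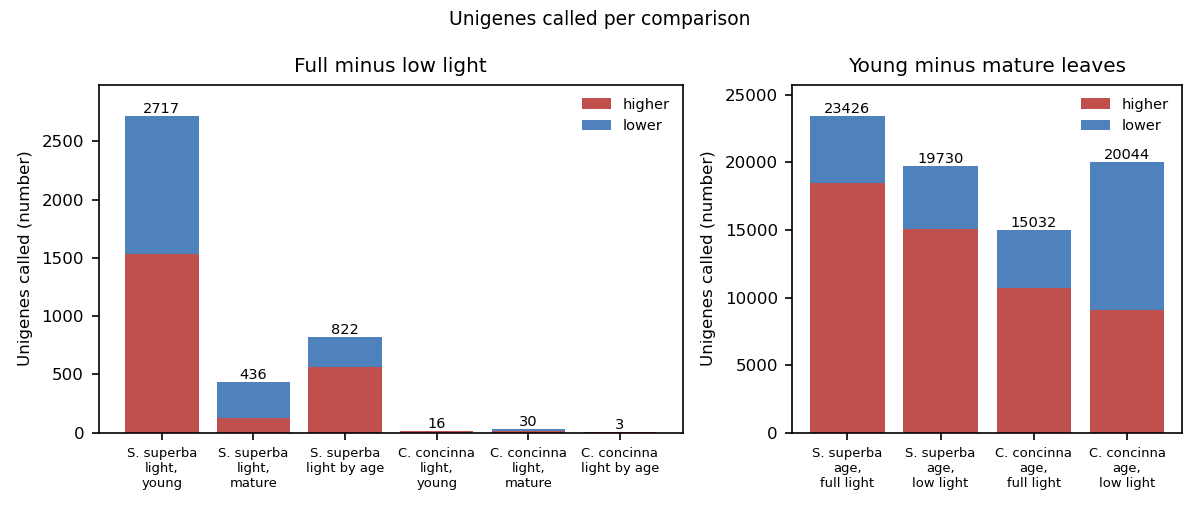
Number of unigenes called higher and lower by limma (y axis) per comparison and species (x axis), as stacked bars with higher in red and lower in blue. The panel for light, which includes light by age, and the panel for young minus mature have separate y axes. Age comparisons gave 15032 to 23426 calls and the light panel 3 to 2717.

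In mature leaves of S. superba, the class II small heat shock protein CL2489.Contig3 stood at 48.9 ± 29.7 FPKM in full and 1.77 ± 0.72 in low light (log2 fold change 4.05, SE 0.46, adjusted p = 0.00424), and a class I member (CL529.Contig2) at 142 ± 83.6 against 8.68 ± 4.01. An (E)-beta-ocimene/myrcene synthase (Unigene22204), which makes volatile monoterpenes, rose to 84.3 ± 33 from 9.81 ± 4.27 (adjusted p = 0.0118), and a putative Acyl-CoA sterol acyl transferase 1 (CL7359.Contig2) to 204 ± 161 from 10.2 ± 5.41. A putative glutathione S-transferase (Unigene23863), a detoxifying enzyme, fell to 1.13 ± 1.52 from 57.6 ± 20.6 (log2 fold change -4.95, SE 0.51, adjusted p = 0.00355), and monothiol glutaredoxin-S1 (CL4179.Contig1) to 0.37 ± 0.286 from 22.3 ± 16.5. A putative anthocyanidin reductase (Unigene3742), of proanthocyanidin synthesis, stood at 10.8 ± 7.57 against 100.3 ± 35, and Chlorophyll a-b binding protein 40 (Unigene28445) at 0.13 ± 0.225 against 11 ± 4.86. An amino acid selective channel protein (CL2153.Contig1) was listed at 0 in the 3 full light libraries and at 79.1, 34.2 and 55.3 FPKM in those in low light, and a chlorophyll a-b binding protein of LHCII type 1 (Unigene34492) was listed at 0 against 7.92, 5.73 and 16.9.

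Among 163 heat shock and chaperone unigenes tested, 12 were higher and 1 lower (list-alone 50 and 7, camera adjusted p = 3.51e-14, estimated-correlation adjusted p = 0.202), against 27 and 1 after median-ratio rescaling and 5 and 0 without the low light libraries numbered 1. For antenna proteins the counts were 0 higher and 4 lower of 35 (list-alone 0 and 23, camera adjusted p = 2.41e-14, estimated-correlation adjusted p = 0.245). Photosystem subunits showed 0 higher and 1 lower of 40 (list-alone 0 and 3, camera adjusted p = 0.385, estimated-correlation adjusted p = 0.839). The terpenoid list gave 0 higher and 0 lower of 26 (list-alone 0 and 0, camera adjusted p = 0.0129, estimated-correlation adjusted p = 0.483), with 0 and 7 at unadjusted p under 0.05, and its camera call ended without the low light libraries numbered 1 (adjusted p = 0.0742). Its median of -0.45 was below 0, while the ocimene synthase above, which its name pattern did not take in, rose. In all, limma called 436 of 50970 unigenes tested, 130 higher and 306 lower in full light, and in 15.3% of unigenes the groups did not overlap. The split followed the scaling, since 29.8% of the changed unigenes were higher as deposited, 41.8% after median-ratio rescaling and 43.3% after quantile normalization. Calls fell to 120 without the low light libraries numbered 1, and a single library left out, young full light replicate 1, 2 or 3, mature full light replicate 2 or 3, young low light replicate 2 or 3 or mature low light replicate 1, left 143 to 278. A fit on the 6 mature libraries alone called 4.

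Some calls ended with 1 library left out, given as the log2 fold change with all libraries, then fold change and adjusted p without it. They were those of the class II small heat shock protein CL4946.Contig2 (3.30 to 2.91, 0.0652 without mature full light replicate 3), at 297 ± 155 against 29.6 ± 14.8 FPKM, and of a myrcene synthase (CL1474.Contig2, 3.21 to 3.22, 0.099 without mature full light replicate 2), at 52.2 ± 45.3 against 4.14 ± 3.19. Without the same library the calls ended for the chloroplast photosystem II PsbR (CL4728.Contig2, -2.44 to -2.28, 0.0892), at 265 ± 121 against 1475 ± 799, and the chlorophyll synthesis enzyme protochlorophyllide reductase (CL742.Contig1, -2.39 to -2.09, 0.0959), at 7.43 ± 6.11 against 39.6 ± 19. Without mature low light replicate 1 they were the anthocyanidin reductase (-3.29 to -3.24, 0.0545), 3-ketoacyl-CoA synthase 4 (CL7948.Contig1, 3.37 to 3.07, 0.11), at 17.6 ± 11.4 against 0.857 ± 1.48, Protein P21 (CL2082.Contig5, -4.99 to -4.50, 0.103), at 3.21 ± 5.06 against 109 ± 76.9, and the cell wall protein extensin-2 (Unigene5735, -3.59 to -2.95, 0.0993), at 4.95 ± 5.03 against 67.6 ± 56.7. Summed clusters took adjusted p to 0.0958 for CL529.Contig2, 0.0876 for the myrcene synthase and 0.0597 for Protein P21. A pseudocount of 0.1 gave 0.063 for the ocimene synthase, 0.108 for the myrcene synthase, 0.0943 for 3-ketoacyl-CoA synthase 4 and 0.0525 for Protein P21, and median-ratio rescaling 0.0587 for the reductase CL742.Contig1.

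Whether light acted differently at the 2 ages was tested directly. Of 19 heat shock and chaperone unigenes of S. superba called for light by age, 5 had the light effect called at both ages, lower in full light in young and higher in mature leaves. In young leaves the list had 8 higher and 16 lower of 163 (list-alone 10 and 18, camera adjusted p = 0.0817, estimated-correlation adjusted p = 0.686). CL4946.Contig2 stood at 26.2 ± 17.5 FPKM in full and 710.2 ± 262 in low light in young leaves, against 297 ± 155 and 29.6 ± 14.8 in mature leaves (difference of log2 fold changes -8.14, SE 0.78, adjusted p = 0.0034). CL2489.Contig2 and CL2489.Contig3 differed by -7.88 and -7.86. Among 163 heat shock and chaperone unigenes tested, 2 were higher and 17 lower (list-alone 7 and 42, camera adjusted p = 7.84e-10, estimated-correlation adjusted p = 0.225). Photosystem subunits had 0 higher and 1 lower of 40 (list-alone 0 and 4, camera adjusted p = 3.79e-11, estimated-correlation adjusted p = 0.214), with a list median of -1.17. The cell cycle list had 13 higher and 0 lower of 183 (list-alone 25 and 1, camera adjusted p = 1.95e-06, estimated-correlation adjusted p = 0.435), with a median of 0.62. Without the low light libraries numbered 1 the heat shock counts were 1 and 9 and those of the cell cycle 4 and 0. Organelle-encoded and ribosomal RNA had a median of 0.24 for light in mature leaves (camera adjusted p = 0.0329, estimated-correlation adjusted p = 0.522) and -0.53 for light by age (camera adjusted p = 0.0195, estimated-correlation adjusted p = 0.52), 2 calls that ended without the same libraries (adjusted p = 0.258 and 0.111). The median of all unigenes was 0.17 as deposited and 0.03 after median-ratio rescaling.

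**Figure D4:**
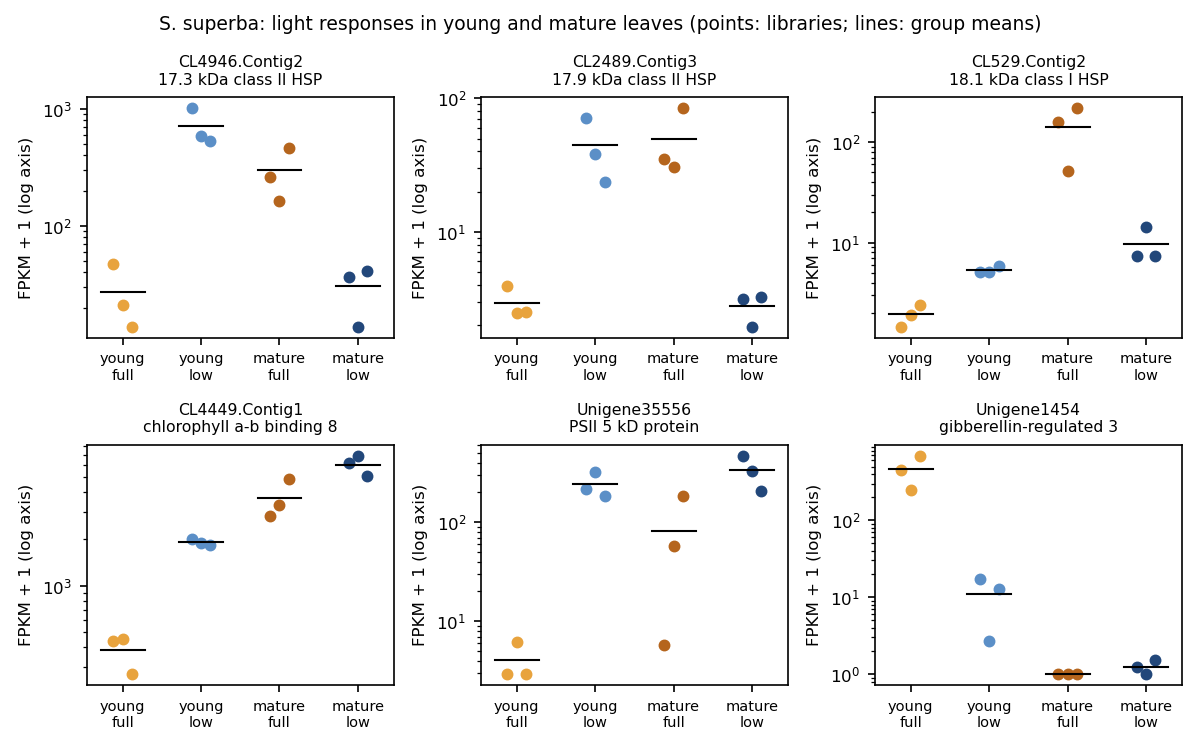
FPKM + 1 per library (y axis, log scale) of 6 S. superba unigenes in the 4 groups of 3 libraries (x axis), with points for libraries and horizontal lines for group means. Points of the class II small heat shock protein CL4946.Contig2 lie lower in full than in low light in young leaves and higher in full than in low light in mature leaves.

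The gibberellin-regulated protein Unigene1454 and inositol oxygenase 1 (Unigene8528, difference 4.87, adjusted p = 0.0143) rose in full light in young leaves and had group means of at most 1.57 FPKM in mature ones. In all, limma called 822 of 50970 unigenes tested, 564 with a more positive and 258 with a more negative light effect in young leaves. The split followed the scaling, since 68.6% of the changed unigenes were more positive as deposited, 48.7% after median-ratio rescaling and 50.1% after quantile normalization. Without young full light replicate 1, 2 or 3, mature full light replicate 2 or 3, young low light replicate 2 or 3 or mature low light replicate 1 or 3, calls numbered 71 to 519, lowest without young low light replicate 2. The low light libraries numbered 1 left out gave 298, and a pseudocount of 0.1 gave 476. Of 25 named unigenes, 17 lost their call with a library left out and 0 turned. For 16 of these it was young low light replicate 2 that weakened them most, and for Chlorophyll a-b binding protein 40 (Unigene28445) young full light replicate 1. Light responses of the 2 ages shared 38 unigenes with the same direction, 8 higher and 30 lower (3.92 and 7.08 for independent lists), and 21 with opposite directions (12.2). Fold changes correlated across unigenes with a Pearson r of 0.09 and a Spearman rho of 0.07, with no p because genes are not independent replicates.

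The age comparisons asked how expanding and mature leaves differ. In S. superba most called cell wall, cell cycle and lignin unigenes were higher in young leaves, and most called photosynthesis and carotenoid unigenes in mature leaves. In full light the proline-rich protein 4 (CL4111.Contig1), a cell wall protein, was listed at 0 in the 3 mature libraries and at 1534, 1288 and 1153 FPKM in the young ones. Cyclin-D3-1 (Unigene6900), which promotes entry into the cell cycle, stood at 235 ± 69.9 in young leaves and, in mature leaves, at 0.11 ± 0 (log2 fold change 7.68, SE 0.27, adjusted p = 1.63e-08). Laccase-12 (CL937.Contig1), of lignin polymerisation, stood at 114 ± 7.34 against 0.0367 ± 0.0351, GDSL esterase/lipase At4g28780 (Unigene11184) at 586 ± 286 against 0.0167 ± 0.0289, and leucoanthocyanidin dioxygenase (Unigene29595), of anthocyanin synthesis, at 633 ± 239 against 3.9 ± 3.72. Isoprene synthase (Unigene5208), which makes the volatile isoprene, was higher in mature leaves, at 602 ± 301 against 0.13 ± 0.225 (log2 fold change -8.94, SE 0.72, adjusted p = 2.75e-06). The same direction held for a Rubisco small subunit (CL6064.Contig1) at 9335 ± 6056 against 65.1 ± 22.2, dehydrodolichyl diphosphate synthase 6 (Unigene2085) at 1000.4 ± 315 against 0.573 ± 0.397, and catalase isozyme 3 (CL2021.Contig2), which breaks down hydrogen peroxide, at 299 ± 108 against 1.97 ± 1.01. Protochlorophyllide reductase (CL742.Contig1) went the other way, at 294 ± 27.9 in young and 7.43 ± 6.11 in mature leaves, and beta-carotene isomerase D27 (Unigene1546), of strigolactone synthesis, stood at 219 ± 3.47 in mature against 6.11 ± 1.83 in young leaves.

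Among 183 cell cycle unigenes tested, 140 were higher and 2 lower (list-alone 144 and 2, camera adjusted p = 4.77e-12, estimated-correlation adjusted p = 0.245), the latter direction meaning higher in mature leaves. Cell wall expansion showed 72 higher and 4 lower of 106 (list-alone 76 and 4, camera adjusted p = 1.37e-06, estimated-correlation adjusted p = 0.265), and phenylpropanoid and lignin synthesis 43 higher and 1 lower of 64 (list-alone 43 and 1, camera adjusted p = 1.05e-05, estimated-correlation adjusted p = 0.396). Among 37 Calvin cycle and Rubisco unigenes tested, 2 were higher and 26 lower (list-alone 2 and 26, camera adjusted p = 2.46e-19, estimated-correlation adjusted p = 0.173). Photosystem subunits had 0 higher and 29 lower of 40 (list-alone 1 and 30, camera adjusted p = 3.62e-17, estimated-correlation adjusted p = 0.173), and carotenoid synthesis 4 higher and 16 lower of 24 (list-alone 4 and 17, camera adjusted p = 1.41e-09, estimated-correlation adjusted p = 0.225). Antenna proteins gave 2 higher and 13 lower of 35 (list-alone 2 and 13, camera adjusted p = 6.76e-06, estimated-correlation adjusted p = 0.483), a camera call that ended under quantile normalization (adjusted p = 0.0657). Cuticle and wax unigenes showed 39 higher and 4 lower of 65 (list-alone 40 and 5, camera adjusted p = 0.00124, estimated-correlation adjusted p = 0.294). Markers of other tissues moved with age as well, with 15 higher and 0 lower of 24 (list-alone 15 and 0, camera adjusted p = 0.0189, estimated-correlation adjusted p = 0.413) for vascular and secondary wall genes, among them fasciclin-like arabinogalactan protein 13 (Unigene2003) at 88.6 ± 52.8 against 0.070 ± 0.121, and 1 higher and 8 lower of 30 (list-alone 1 and 3, camera adjusted p = 4.93e-05, estimated-correlation adjusted p = 0.312) for organelle-encoded and ribosomal RNA. The median of all unigenes was 0.55, and 0.09 after median-ratio rescaling, so list medians such as 1.71 for the cell cycle and -2.54 for photosystems stand relative to that shift.

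In low light, the metallothionein Unigene13627 stood at 20671 ± 4476 in mature and 136 ± 59.4 in young leaves (log2 fold change -7.31, SE 0.42, adjusted p = 4.75e-07). Rubisco activase (CL430.Contig4), which keeps Rubisco active, stood at 1982 ± 354 against 15.2 ± 3.42, granule-bound starch synthase 1 (Unigene6753), of amylose synthesis, at 574 ± 127 against 2.15 ± 1.18, and 15-cis-phytoene desaturase (Unigene35454), of carotenoid synthesis, at 76.5 ± 15 against 3.43 ± 1.03. Chalcone synthase (Unigene23365), the entry enzyme of flavonoid synthesis, stood at 195 ± 75.7 in young and 0.417 ± 0.365 in mature leaves, and Cyclin-D3-1 at 118 ± 32.7 against 0.58 ± 0.218. Cell wall expansion showed 75 higher and 4 lower of 106 (list-alone 79 and 5, camera adjusted p = 1.63e-09, estimated-correlation adjusted p = 0.225), the Calvin cycle 1 higher and 22 lower of 37 (list-alone 1 and 22, camera adjusted p = 2.55e-16, estimated-correlation adjusted p = 0.173) and photosystem subunits 1 higher and 14 lower of 40 (list-alone 1 and 14, camera adjusted p = 6.99e-08, estimated-correlation adjusted p = 0.241). Vascular markers had 14 higher and 0 lower of 24 (camera adjusted p = 0.0106, estimated-correlation adjusted p = 0.353). Organelle-encoded and ribosomal RNA had 4 higher and 3 lower of 30 (camera adjusted p = 0.0276, estimated-correlation adjusted p = 0.52), a call ended by median-ratio rescaling (adjusted p = 0.0572). In all, limma called 23426 of 50970 unigenes tested, 18496 higher and 4930 lower in young leaves in full light, and 19730 of 50970 unigenes tested, 15046 higher and 4684 lower in low light. In 53.3% and 50.9% of unigenes the groups did not overlap. The split followed the scaling: in full light 79% of the changed unigenes were higher as deposited, 57.3% after median-ratio rescaling and 53.3% after quantile normalization, and in low light the shares were 76.3%, 57.1% and 54%, with a median of all unigenes of 0.39 as deposited and 0.06 after median-ratio rescaling. A mean FPKM of at least 5, with fewer unigenes tested, gave 14412 and 12159. Both lights called 15017 unigenes in the same direction and 135 in opposite ones (3155 for independent lists), and fold changes correlated across unigenes with a Pearson r of 0.78 and a Spearman rho of 0.71.

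In C. concinna few unigenes passed the test for light. In young leaves, higher in full light were an ankyrin repeat-containing protein (CL750.Contig2), at 18.2 ± 4.77 FPKM against 0.0833 ± 0.085 (log2 fold change 4.12, SE 0.37, adjusted p = 0.00225). So were Cellulose synthase-like protein E6 (CL6913.Contig1), at 31.9 ± 5.0 against 2.82 ± 2.6, and NAC transcription factor 25 (CL6619.Contig4), at 13.3 ± 0.68 against 1.26 ± 0.715. The contig of scarecrow-like protein 21 (CL2988.Contig2) was listed at 0 in the 3 young low light libraries and at 28.6, 13.4 and 6.63 FPKM in full light. Histone H2B.11 (CL1900.Contig1), a packaging protein of DNA, was lower in full light, at 62.5 ± 17.1 against 313 ± 85 (log2 fold change -2.31, SE 0.28, adjusted p = 0.014). Among 323 cytosolic and plastid ribosomal protein unigenes tested, 0 were higher and 0 lower (list-alone 5 and 50, camera adjusted p = 4.56e-38, estimated-correlation adjusted p = 0.0831), where 10 and 112 had an unadjusted p under 0.05. Antenna unigenes had 0 higher and 0 lower of 52 (list-alone 0 and 11, camera adjusted p = 5.54e-21, estimated-correlation adjusted p = 0.257), with 1 and 19 at unadjusted p under 0.05, and photosystem subunits 0 higher and 0 lower of 72 (list-alone 0 and 2, camera adjusted p = 1.84e-17, estimated-correlation adjusted p = 0.164), with 2 and 16. The cell cycle list gave 0 higher and 1 lower of 215 (list-alone 6 and 26, camera adjusted p = 3.62e-06, estimated-correlation adjusted p = 0.352), and its median of 0.10 and mean of -0.05 lay on opposite sides of 0. The median of all unigenes was 0.34, and 0.05 after median-ratio rescaling. Relative to that shift the medians of ribosomal proteins, at -0.44, antenna, at -0.54, and photosystems, at -0.60, were low. Phenylpropanoid unigenes showed 0 higher and 0 lower of 64 (list-alone 0 and 0, camera adjusted p = 0.0332, estimated-correlation adjusted p = 0.648), with 3 and 4 at unadjusted p under 0.05, and a median of 0.22 although the test put the list below the others, a call that ended after median-ratio rescaling (adjusted p = 0.0925). Organelle-encoded and ribosomal RNA showed 0 higher and 0 lower of 35 (list-alone 0 and 0, camera adjusted p = 5.50e-06, estimated-correlation adjusted p = 0.257), with 0 and 3 at unadjusted p under 0.05.

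In mature leaves of C. concinna, a metallothionein (Unigene16265) rose in full light, to 14.9 ± 6.59 from 0.0567 ± 0.0981 FPKM (log2 fold change 3.82, SE 0.39, adjusted p = 0.00354), as did a Rubisco small subunit (Unigene7495), to 13 ± 7.3 from 0.497 ± 0.315 (adjusted p = 0.00656). NAC transcription factor 25 (CL6619.Contig4) rose to 26.9 ± 6.25 from 4.5 ± 0.864. Protein RADIALIS-like 2 (Unigene8154) stood at 8.94 ± 10.8 against 157 ± 44.7 and protein RADIALIS-like 3 (Unigene17301), both of the MYB-related family, at 74.7 ± 20.3 against 1135 ± 552. The scarecrow-like contig stood at 27.4 ± 16.2 against 0.53 ± 0.461, and ER membrane protein complex subunit 4 (CL1298.Contig1) at 65.6 ± 44.3 against 4.53 ± 1.39. The contig of the SUMO-conjugating enzyme SCE1 (CL6053.Contig2) was listed at 0 in low light and at 5.51, 27.1 and 39.5 in full light, and that of ER membrane protein complex subunit 3 (CL1691.Contig2) was listed at 0 in every library but the mature low light ones, at 17.4, 39.5 and 25.9. Ribosomal proteins showed 1 higher and 0 lower of 323 (list-alone 1 and 0, camera adjusted p = 3.81e-05, estimated-correlation adjusted p = 0.567), with 5 and 34 at unadjusted p under 0.05. The test put this list lower, at a median of -0.25, and the call ended under quantile normalization (adjusted p = 0.0524). Antenna proteins gave 1 higher and 0 lower of 52 (list-alone 12 and 0, camera adjusted p = 0.117, estimated-correlation adjusted p = 0.855), with a median of -0.24 but a mean of 0.12, and were called higher after median-ratio rescaling (adjusted p = 0.0464). Vascular markers had a median of -0.31 (camera adjusted p = 0.033, estimated-correlation adjusted p = 0.704), a call that ended without mature low light replicate 2 (adjusted p = 0.951). Without that library camera newly called 6 lists higher in full light, with adjusted p at the preset and then with an estimated correlation. They were antenna (adjusted p = 4.20e-06 and 0.601), photosystems (0.000199 and 0.434), cuticle and wax (6.34e-05 and 0.135), cell wall (0.0291 and 0.752), MYB and bHLH (0.0414 and 0.731) and organelle-encoded and ribosomal RNA (0.0392 and 0.674). The last list had a median of -0.65 for light by age (camera adjusted p = 2.86e-05, estimated-correlation adjusted p = 0.257). The light by age test called 3 of 53005 unigenes tested, 2 with a more positive and 1 with a more negative effect in young leaves, with 5725 at unadjusted p under 0.05 and a median of all unigenes of 0.39 (0.02 after median-ratio rescaling). They were CL1691.Contig2 (adjusted p = 0.00419), a second ankyrin repeat contig (CL750.Contig3, adjusted p = 0.0201), at 7.85, 7.18 and 6.71 FPKM in young leaves in full light and listed at 0 in the young low light libraries, and CL3584.Contig1, which is without a usable description (adjusted p = 0.00419), listed at 0 in the mature low light libraries and at 11.1, 10.9 and 10.1 in mature leaves in full light. The last pair was chosen after its values were seen. Calls numbered 5 to 13 without young full light replicate 3, mature full light replicate 1 or 2 or mature low light replicate 1 or 2. As for the split, 66.7% of the changed unigenes were more positive as deposited, 60% after median-ratio rescaling and 42.9% after quantile normalization.

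Summing clusters ended the call of 3 of 5 named contigs in young leaves, and in mature leaves ended 3 and turned 2 of 5. Summed over the cluster, the light effect on the scarecrow-like protein was 0.38 in young (adjusted p = 0.278) and -0.072 in mature leaves, that on NAC transcription factor 25 0.86 and 0.38 (adjusted p = 0.285 and 0.975), that on SCE1 -0.35, and that on subunits 3 and 4 of the ER complex -0.60 and 0.94 (adjusted p = 0.535 and 0.63). The summed ankyrin repeat cluster gave 3.95 (adjusted p = 0.0987). With a library left out, adjusted p rose to 0.0871 for the scarecrow-like protein and 0.129 for Cellulose synthase-like protein E6 without young full light replicate 2, to 0.0565 for histone H2B.11 without young low light replicate 2, to 0.085 for RADIALIS-like 2 without mature low light replicate 3, and to 0.155 for RADIALIS-like 3 and 0.167 for subunit 4 without mature full light replicate 3. Without mature full light replicate 2 it rose to 0.0626 for the scarecrow-like protein, 0.0693 for NAC transcription factor 25 and 0.0693 for SCE1 in mature leaves. A pseudocount of 0.1 gave 0.0563 for the ankyrin repeat protein and 0.0888 for E6 in young leaves, and 0.0809 for NAC transcription factor 25 and 0.0825 for RADIALIS-like 2 in mature ones. Median-ratio rescaling gave 0.0801 for E6. In all, limma called 16 of 53005 unigenes tested, 13 higher and 3 lower in full light in young leaves, with 9484 at unadjusted p under 0.05, and 30 of 53005 unigenes tested, 16 higher and 14 lower in mature leaves, with 3492. A fit on the 6 libraries compared gave 0 limma calls at each age (10125 and 3139 unadjusted), and another split of these libraries gave up to 53 and 229. The groups did not overlap in 26.7% and 10.5% of unigenes, where chance gives 10%. In young leaves 81.2% of the changed unigenes were higher as deposited, 62.5% after median-ratio rescaling and 57.1% after quantile normalization. Calls numbered 66 in young leaves without young low light replicate 1 and 64 in mature leaves without mature low light replicate 2. Without mature full light replicate 2 or 3, young low light replicate 2 or mature low light replicate 1, mature leaves gave 12 to 19. Both ages called 2 unigenes in the same direction, the contigs of the scarecrow-like protein and NAC transcription factor 25, against 0.00392 for independent lists.

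Leaf age changed many more unigenes of C. concinna, with most called cell wall, cuticle, ribosomal and cell cycle unigenes higher in young and most called Calvin cycle unigenes in mature ones. In full light the proline-rich protein 4 (Unigene6825) stood at 4086 ± 1445 FPKM in young and 4.96 ± 8.17 in mature leaves (log2 fold change 10.41, SE 1.08, adjusted p = 2.86e-05), and GDSL esterase/lipase At5g33370 (Unigene28340) at 1742 ± 671 against 0.26 ± 0.182. Expansin-A15 (CL3876.Contig1), which loosens the cell wall, was listed at 0 in the 6 mature libraries and at 154, 586 and 473 in young leaves in full light. Flavonol synthase (Unigene32275) stood at 1734 ± 165 against 23 ± 14.8 and histone H3.2 (Unigene5291) at 80.7 ± 27 against 0.367 ± 0.201. Higher in mature leaves were galactinol synthase (CL4158.Contig3), of raffinose synthesis, at 1026 ± 722 against 2.72 ± 2.16 (log2 fold change -8.12, SE 0.54, adjusted p = 1.02e-06). They also included metallothionein-like protein 3 (Unigene4583) at 8999 ± 3652 against 125 ± 125, granule-bound starch synthase 1 (Unigene29942) at 1155 ± 553 against 39.2 ± 18.4, and the Calvin cycle enzyme phosphoribulokinase (CL6353.Contig1) at 75.5 ± 18.3 against 4.48 ± 3.87. Protein TRANSPARENT TESTA 12 (Unigene2617), a transporter of flavonoids, was listed at 0 in the young libraries in full light and at 248, 759 and 635 in the mature ones.

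Among 114 cell wall expansion unigenes tested, 84 were higher and 4 lower (list-alone 90 and 6, camera adjusted p = 5.61e-19, estimated-correlation adjusted p = 0.209). Cuticle and wax showed 68 higher and 4 lower of 115 (list-alone 73 and 5, camera adjusted p = 1.38e-13, estimated-correlation adjusted p = 0.0831). Ribosomal proteins gave 179 higher and 13 lower of 323 (list-alone 195 and 19, camera adjusted p = 1.33e-11, estimated-correlation adjusted p = 0.268) and the cell cycle 116 higher and 4 lower of 215 (list-alone 133 and 8, camera adjusted p = 2.31e-10, estimated-correlation adjusted p = 0.257). Among 51 Calvin cycle and Rubisco unigenes tested, 2 were higher and 20 lower (list-alone 3 and 23, camera adjusted p = 7.49e-10, estimated-correlation adjusted p = 0.257). Photosystem subunits had 2 higher and 24 lower of 72 (list-alone 2 and 24, camera adjusted p = 1.72e-09, estimated-correlation adjusted p = 0.257), and antenna proteins 2 higher and 15 lower of 52 (list-alone 2 and 17, camera adjusted p = 6.65e-05, estimated-correlation adjusted p = 0.695). In low light, galactinol synthase stood at 614 ± 226 in mature against 0.257 ± 0.0924 in young leaves, leaf ferredoxin--NADP reductase (CL6765.Contig2), of photosynthetic electron transport, at 843 ± 67.7 against 91.1 ± 39.3, and RADIALIS-like 2 at 157 ± 44.7 against 0.0367 ± 0.0635. Higher in young leaves were histone H2A.1 (Unigene10621), at 238 ± 132 against 1.19 ± 2.07, the light-signalling factor HY5 (Unigene17288), at 24.6 ± 11.5 against 2.92 ± 2.0, and a chlorophyll a-b binding protein (Unigene2634), at 2254 ± 705 against 409.5 ± 331 (adjusted p = 0.000828). The cell wall list showed 79 higher and 4 lower of 114 (list-alone 85 and 5, camera adjusted p = 9.70e-22, estimated-correlation adjusted p = 0.164), cuticle and wax 69 higher and 5 lower of 115 (list-alone 71 and 6, camera adjusted p = 2.97e-17, estimated-correlation adjusted p = 0.0831). Ribosomal proteins had 197 higher and 19 lower of 323 (list-alone 202 and 22, camera adjusted p = 4.03e-22, estimated-correlation adjusted p = 0.164) and the Calvin cycle 2 higher and 30 lower of 51 (list-alone 4 and 31, camera adjusted p = 2.02e-05, estimated-correlation adjusted p = 0.416). Antenna proteins gave 18 higher and 15 lower of 52 (list-alone 19 and 15, camera adjusted p = 0.172, estimated-correlation adjusted p = 0.855), and 20 higher and 11 lower without mature low light replicate 2 (camera adjusted p = 0.00997, estimated-correlation adjusted p = 0.775). Vascular and secondary wall markers moved with age here too, with 11 higher and 2 lower of 23 (list-alone 13 and 2, camera adjusted p = 0.0105, estimated-correlation adjusted p = 0.648) in full and 10 higher and 4 lower of 23 (camera adjusted p = 0.00782, estimated-correlation adjusted p = 0.648) in low light, the latter call ended by quantile normalization (adjusted p = 0.0512). Organelle-encoded and ribosomal RNA gave 1 higher and 2 lower of 35 (camera adjusted p = 0.0353, estimated-correlation adjusted p = 0.648) in full light, a call that ended after median-ratio rescaling (adjusted p = 0.0808).

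In all, limma called 15032 of 53005 unigenes tested, 10691 higher and 4341 lower in young leaves in full light, and 20044 of 53005 unigenes tested, 9056 higher and 10988 lower in low light. The groups did not overlap in 44.2% and 48.8% of unigenes. The median of all unigenes was 0.17 in full and -0.27 in low light, and -0.08 and -0.14 after median-ratio rescaling. In full light 71.1% of the changed unigenes were higher as deposited, 51.7% after median-ratio rescaling and 50.6% after quantile normalization, and 55% were higher with the proline-rich CL2130.Contig2 removed and the libraries rescaled. A mean FPKM of at least 5, with fewer unigenes tested, gave 9153 and 10289. Leaving out mature low light replicate 2 gave 16292 and 22731. Both lights called 10768 unigenes in the same direction and 25 in opposite ones (2958 for independent lists), with a Pearson r of 0.84 and a Spearman rho of 0.80 across unigenes.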

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

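The tests of small heat shock and other chaperone clusters taken apart were chosen only after the result was seen, as was summing contigs for single genes. Each result was flagged as its light effect differed between ages by limma's light by age test, given as the difference of log2 fold changes.

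Of 19 heat shock and chaperone unigenes called in S. superba, 16 were lower in full light in young and higher in mature leaves, and 5 of the 19 had both simple effects called. Being called on the difference favours opposite signs, and many share clusters, so the 16 of 19 are weak evidence. Library scaling is argued against, since 18 kept call and sign under median-ratio rescaling and 19 under quantile normalization. With 1 library left out, 0 fell under 1 log2 unit or turned, but 8 (without young low light replicate 2) to 18 stayed called. So signs did not rest on 1 library, but some calls did. Reads shared between contigs were tested by summing clusters: 3 of 6 kept call and sign, exactly the bound set beforehand, which by its wording counted against shared reads. Reading this tie as undecided was chosen only after the value was seen. Apart, 3 of 3 small heat shock protein clusters kept it (CL4946 -8.09, adjusted p = 0.00267, CL2489 -8.23, adjusted p = 0.00188, CL529 -4.16, adjusted p = 0.0249) and 0 of 3 other chaperone clusters (CL148 -0.71, adjusted p = 0.344, CL1396 -0.44, adjusted p = 0.61, CL6390 2.04, adjusted p = 0.395), where shared reads stay a candidate explanation. As a hypothesis, small heat shock genes may respond to light in opposite ways in young and mature leaves, while temperature or time of day at sampling, which the labels do not give, was not tested and stays open.

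Group means below are FPKM in full and low light (n = 3 each), in young and then in mature leaves. Among the heat shock proteins the differences were -8.14 for CL4946.Contig2 (26.2 and 710.2, then 297 and 29.6) and -7.77 for CL4946.Contig3 (6.69 and 216, then 114 and 14.4). CL2489.Contig2 gave -7.88 (5.16 and 124, then 99 and 6.83) and CL2489.Contig3 -7.86 (1.95 and 43.4, then 48.9 and 1.77). The chaperone regulator BAG 6 (CL1982.Contig4) differed by -7.03 (2.26 and 149, then 168 and 46). A dnaJ homolog subfamily C member (CL6390.Contig1) went the other way, at 4.80 (120 and 2.85, then 0.60 and 0.607).

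Of other functions, a putative glutathione S-transferase (Unigene23863) differed by 5.15 (73.3 and 71.7 in young, 1.13 and 57.6 in mature leaves). Inositol oxygenase 1 (Unigene8528) gave 4.87 (52.1 and 2.34 in young, 0.12 and 1.57 in mature leaves). 3-Ketoacyl-CoA synthase 17 (Unigene29370) had a difference of 4.49 (24.1 and 0.030 in young, 0.0167 and 0.0167 in mature leaves). The putative anthocyanidin reductase (Unigene3742) stood at 4.37 (314 and 142 in young, 10.8 and 100.3 in mature leaves). An auxin-repressed protein (Unigene6549) differed by 3.52 (4.22 and 1.14 in young, 0.263 and 5.38 in mature leaves). Histone H4 (CL443.Contig9) gave 3.45 (275 and 67.1 in young, 1.4 and 6.19 in mature leaves). Chlorophyll a-b binding protein 40 (Unigene28445) differed by 3.22 (4.98 and 6.17 in young, 0.13 and 11 in mature leaves). Transcription factor MYB34 (Unigene21065) gave 2.50 (15.6 and 11.4 in young, 0.607 and 5.93 in mature leaves). TRANSPARENT TESTA GLABRA 1 (CL8169.Contig2) differed by 1.93 (118 and 31.3 in young, 18.6 and 19.4 in mature leaves). A lipoxygenase (CL1432.Contig1) gave 1.77 (146 and 36.4 in young, 30.1 and 26.3 in mature leaves). Rubisco activase 1 (Unigene11021) differed by 1.59 (18.9 and 6.14 in young, 810.2 and 876 in mature leaves). More negative in young leaves, a cinnamoyl-CoA reductase (Unigene13533) differed by -4.53 (2.61 and 52.8, then 0.197 and 0.0833). Expansin-A4 (CL2042.Contig4) gave -3.74 (4.47 and 47, then 1.26 and 0.787). A putative invertase inhibitor (Unigene717) differed by -3.37 (2.53 and 6.25, then 15 and 1.9). Fasciclin-like arabinogalactan protein 11 (CL1999.Contig1) gave -2.51 (1.46 and 11, then 1.94 and 1.61). Oxygen evolving enhancer protein 3 (Unigene5751) gave -2.01 (7.06 and 26.6, then 77.7 and 67.2). The ultraviolet-B receptor UVR8 (CL470.Contig2) differed by -1.65 (14 and 26.3, then 11.6 and 6.46).

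Fitted values that rest on a group listed at 0 are no bound on the difference. They were 5.96 for the gibberellin-regulated protein Unigene1454, listed at 0 in mature leaves in full light, 4.73 for the amino acid selective channel protein CL2153.Contig1, likewise, and in C. concinna 4.76 for subunit 3 of the ER membrane protein complex (CL1691.Contig2), listed at 0 outside mature low light. Summed over their clusters, CL2153 gave 0.30 (adjusted p = 0.533) and CL1691 gave 0.22 (adjusted p = 0.759). Summing also ended the calls of expansin-A4 (adjusted p = 0.118) and UVR8 (0.0522). A pseudocount of 0.1 ended those of CL6390.Contig1 (0.0862), the cinnamoyl-CoA reductase (0.0954), UVR8 (0.0608), expansin-A4 (0.109), histone H4 (0.0771), the invertase inhibitor (0.072) and the fasciclin-like protein (0.0698). Median-ratio rescaling ended those of the invertase inhibitor (0.0584) and the lipoxygenase (0.0574). The library that weakened a call most, left out, was young low light replicate 2 for BAG 6, CL6390.Contig1 and those in the paragraph above but 3. It ended these calls (adjusted p of 0.0544 to 0.124). Of the 3, inositol oxygenase 1 and 3-ketoacyl-CoA synthase 17 kept theirs, and that of Chlorophyll a-b binding protein 40 ended without young full light replicate 1 (0.0701).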

How the results depend on the processing

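Later settings, listed with the rule for named genes, were tests chosen only after the data were seen. Of the settings fixed at the start, applied to the counts, overlaps, breadth values and lists, 104 kept their side of the test or stayed within 1.5 times, 27 moved further and 1 changed sign, and of the later ones 23 stayed and 5 moved. With each library left out, 135 stayed and 33 moved. Of single gene results, 294 kept their call under the settings fixed at the start and 36 lost it, 34 lost it when the library that weakened it most was left out, while summing contigs kept 37, ended 15 and turned 3. Absolute depth was unknown, which leaves the error of low values open. With 200 unigenes changed, simulated light changes of 1 (log2) were called in only 5.97% (S. superba, young) and 1.49% (C. concinna, young) of cases. This cannot be carried over to S. superba, where that test called 2717 unigenes.

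In S. superba a pseudocount of 0.1 gave 1303 calls for light in young leaves (2717 as reported), 476 for light by age (822) and 25 shared light calls (38). Without the low light libraries numbered 1, fewer samples gave 120 calls for light in mature leaves (436) and 298 for light by age. Fitting only the 6 mature libraries gave 4. A mean FPKM of at least 5 tested fewer unigenes and gave 14412 age calls in full light (23426) and 12159 in low light (19730). With an estimated correlation 0 of 52 camera calls held. Summing turned gigantea (CL1709.Contig1) to -0.066 for light in young leaves. In C. concinna a pseudocount of 0.1 gave 30 calls for light in young leaves (16) and 1 shared light call (2). A mean FPKM of at least 5 gave 6 calls for light in young and 13 in mature leaves (30), 1 for light by age (3), 9153 for age in full (15032) and 10289 in low light (20044), and 6991 shared age calls (10768). Light by age gave 5 calls after median-ratio rescaling and 7 after quantile normalization, which gave 46 for light in mature leaves. Summed contigs gave 10, 15 and 0 calls for light in young leaves, in mature leaves and by age, the last with 4967 at unadjusted p under 0.05, and turned CL2988.Contig2 to -0.072 and CL6053.Contig2 to -0.35 in mature leaves. Only the 6 libraries compared gave 0 limma calls at each age, with 10125 and 3139 at unadjusted p under 0.05. Counted at FPKM of at least 5, young leaves had 1195 more unigenes than mature ones (exact permutation p = 0.355), against -2214 at 1, both within the spread. With an estimated correlation 0 of 57 camera calls held.

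With each library left out in turn, S. superba gave 481 to 3349 calls for light in young and 143 to 492 in mature leaves, 20709 to 23590 for age in full and 15283 to 20690 in low light and 71 to 761 for light by age. Its breadth differed by 6224 to 7528 unigenes and the share of the 100 most abundant by -14.8 to -13.1 points. C. concinna gave 11 to 66, 12 to 64, 11212 to 16292, 13791 to 22731 and 2 to 13 calls in the same order, -3379 to -905 unigenes and -19.9 to -15.9 points.

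Of 18 pairs with 1 replicate number, 3 correlated over 0.1 in S. superba and 5 in C. concinna. The 3 joined both ages of 1 light, so pairing stays open. Of 12 libraries, 4 and 5 correlated best with their own number. As a block, the number gave 262 calls for light in mature leaves, 331 for light by age and 25 shared light calls in S. superba, and in C. concinna 10 and 10 calls for light in young and mature leaves and 1 shared. It ended 3 single gene calls for light in mature leaves of S. superba (CL2082.Contig5, CL742.Contig1, Unigene5735) and 9 for light by age (Unigene28445, Unigene717, Unigene21065, CL470.Contig2, CL2042.Contig4, CL443.Contig9, CL1432.Contig1, CL1999.Contig1, CL8169.Contig2). In C. concinna it ended 1 in young (CL6913.Contig1) and 4 in mature leaves (CL6619.Contig4, Unigene8154, Unigene17301, CL1298.Contig1). No other count moved over 1.5-fold and no other such call ended.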

Other observations

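The Gene Ontology terms, the comparison named for each list, which is the one with the smallest camera p, and the exact test on sibling contigs were tests chosen only after the result was seen. Higher stands for full light or young leaves. By annotated terms, for nucleosome unigenes the light effect in young leaves was 20 higher and 0 lower of 48 (camera adjusted p = 1.62e-11, adjusted p = 0.383 with an estimated correlation) and a median of 1.06 in S. superba, and in C. concinna 0 higher and 0 lower of 41 (camera adjusted p = 2.99e-37, estimated-correlation adjusted p = 0.0981), with 0 and 32 at unadjusted p under 0.05 and a median of -1.28. The difference between the species was not tested, since their tables were made apart. Terms tested numbered 572 in S. superba and 427 in C. concinna.

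Among the other lists of S. superba, auxin response unigenes numbered 57 higher and 6 lower of 101 for age in full light (57 and 6 over the list alone, camera adjusted p = 0.00946, estimated-correlation adjusted p = 0.483). Starch and sucrose unigenes had 7 higher and 17 lower of 45 for age in full light (list-alone 7 and 18, camera adjusted p = 5.70e-05, estimated-correlation adjusted p = 0.29). Antioxidant enzymes showed 13 higher and 22 lower of 75 for age in full light (list-alone 13 and 22, camera adjusted p = 6.06e-06, estimated-correlation adjusted p = 0.214). Photoprotection gave 11 higher and 14 lower of 61 for age in full light (list-alone 11 and 14, camera adjusted p = 0.0012, estimated-correlation adjusted p = 0.52), with a median of 0.05 and a mean of -0.17 while the test put the list low. Pathogenesis-related unigenes had 6 higher and 1 lower of 242 for light in young leaves (list-alone 3 and 1, camera adjusted p = 0.0276, estimated-correlation adjusted p = 0.52). The chlorophyll synthesis list showed 0 higher and 1 lower of 13 for light in young leaves (list-alone 0 and 1, camera adjusted p = 0.0158, estimated-correlation adjusted p = 0.225). Leaf senescence had 0 higher and 0 lower of 24 for light in mature leaves (list-alone 0 and 0, 6 and 2 at unadjusted p under 0.05, camera adjusted p = 0.0346, estimated-correlation adjusted p = 0.483), a call that ended under quantile normalization (adjusted p = 0.0525). With FPKM as deposited no camera call was made for the remaining lists. Flavonoid unigenes had 3 higher and 0 lower of 68 for light by age (list-alone 6 and 2, camera adjusted p = 0.138), called after median-ratio rescaling (adjusted p = 0.043). Light receptors gave 14 higher and 11 lower of 50 for age in low light (list-alone 14 and 11, camera adjusted p = 0.139), where median (0.11) and mean (0.08) lay above 0 and the test pointed down. Abscisic acid and drought unigenes showed 1 higher and 0 lower of 34 for light in mature leaves (list-alone 1 and 1, camera adjusted p = 0.119). Jasmonate response had 0 higher and 0 lower of 45 for light in mature leaves (list-alone 0 and 4, 0 and 10 at unadjusted p under 0.05, camera adjusted p = 0.12). MYB and bHLH factors gave 1 higher and 3 lower of 147 for light in mature leaves (list-alone 1 and 10, camera adjusted p = 0.0606). Trichome, epidermis and guard cell markers had 16 higher and 1 lower of 27 for age in full light (list-alone 17 and 2, camera adjusted p = 0.0619), likewise called then (adjusted p = 0.0334).

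In C. concinna, terpenoid synthesis had 16 higher and 0 lower of 30 for age in full light (list-alone 16 and 0, camera adjusted p = 3.74e-05, estimated-correlation adjusted p = 0.293). Trichome, epidermis and guard cell markers showed 16 higher and 0 lower of 26 for age in full light (list-alone 17 and 1, camera adjusted p = 0.00178, estimated-correlation adjusted p = 0.257). MYB and bHLH factors had 61 higher and 23 lower of 164 for age in low light (list-alone 62 and 24, camera adjusted p = 0.000187, estimated-correlation adjusted p = 0.371). The auxin response list gave 51 higher and 25 lower of 114 for age in low light (list-alone 51 and 27, camera adjusted p = 0.0030, estimated-correlation adjusted p = 0.414). Flavonoid synthesis had 21 higher and 7 lower of 60 for age in low light (list-alone 22 and 8, camera adjusted p = 0.0127, estimated-correlation adjusted p = 0.371), with a median of -0.07 below and a mean of 0.59 above 0, a call that ended under quantile normalization (adjusted p = 0.0586). Light receptors showed 0 higher and 0 lower of 36 for light in young leaves (list-alone 2 and 0, 10 and 0 at unadjusted p under 0.05, camera adjusted p = 0.00871, estimated-correlation adjusted p = 0.708), ended by median-ratio rescaling (adjusted p = 0.186). Antioxidant enzymes had 0 higher and 0 lower of 86 for light in young leaves (list-alone 0 and 0, 7 and 8 at unadjusted p under 0.05, camera adjusted p = 0.00303, estimated-correlation adjusted p = 0.257), where the median of -0.01 and the mean of 0.04 differed in sign, ended by quantile normalization (adjusted p = 0.604). Photoprotection showed 0 higher and 0 lower of 51 for light by age (list-alone 0 and 0, 11 and 1 at unadjusted p under 0.05, camera adjusted p = 0.00586, estimated-correlation adjusted p = 0.749), ended by median-ratio rescaling (adjusted p = 0.105). Pathogenesis-related unigenes gave 0 higher and 0 lower of 401 for light in young leaves (list-alone 15 and 5, 92 and 16 at unadjusted p under 0.05, camera adjusted p = 0.0306, estimated-correlation adjusted p = 0.781). Starch and sucrose unigenes showed 0 higher and 0 lower of 53 for light in mature leaves (list-alone 0 and 0, 7 and 0 at unadjusted p under 0.05, camera adjusted p = 0.0217, estimated-correlation adjusted p = 0.414). Heat shock and chaperone unigenes gave 0 higher and 0 lower of 205 for light in mature leaves (list-alone 0 and 0, 9 and 8 at unadjusted p under 0.05, camera adjusted p = 0.0115, estimated-correlation adjusted p = 0.781). Carotenoid synthesis had 1 higher and 13 lower of 25 for age in low light (list-alone 1 and 14, camera adjusted p = 0.00378, estimated-correlation adjusted p = 0.648). No camera call was made for chlorophyll synthesis, with 0 higher and 0 lower of 8 for light in mature leaves (list-alone 0 and 0, 0 and 0 at unadjusted p under 0.05, camera adjusted p = 0.154), or abscisic acid and drought, with 8 higher and 2 lower of 27 for age in full light (list-alone 8 and 2, camera adjusted p = 0.461). Nor was one made for jasmonate, with 16 higher and 4 lower of 48 for age in full light (list-alone 18 and 5, camera adjusted p = 0.257), and leaf senescence, with 4 higher and 15 lower of 32 for age in low light (list-alone 4 and 15, camera adjusted p = 0.11), the last called under quantile normalization (adjusted p = 0.0469).

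Mature low light replicate 2 of C. concinna lay towards the young libraries. Over 422 unigenes specific to young leaves, its median was 2.12% of the young mean. The other mature libraries, low by this choice, had 0.195 to 0.507%. Young-leaf RNA mixed in would bring these in 1 proportion. Their excess had an interquartile range of 4.6 (log2), against 0.68 to 1.32 in young libraries. It cannot decide, as the library's lower quartile, 0.35% of the young mean, lay near the 0.32% of mature low light replicates 1 and 3. Extensin-2 (Unigene16568) stood at 439.6 of a young mean of 5000.5 FPKM, but 412.9 in mature full light replicate 2. A GDSL esterase/lipase (Unigene28340) stood at 0.11 of 1451, but Unigene18665 at 228 of 1462. This argues against a mixture as the whole source for such abundant unigenes, and leaves it open for the rest. A leaf at an earlier stage, which labels do not record, stays open, untested.

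In S. superba the low light libraries numbered 1 of both ages deviated together from their groups, with 195 unigenes raised in both, against 27 for the libraries numbered 2 and 33 for those numbered 3. Deviations of this pair correlated at 0.324, yet those of the full light libraries numbered 3 did so at 0.287, and at 0.256 in C. concinna. Carry-over of mature RNA into the young library is argued against, since its excess was a median of 0.447% of the mature value over 44 mature-abundant unigenes (quartiles 0.0664 and 1.56). Sequence variants that move reads between contigs of a cluster cannot be told apart from other sources: 27.5% of raised contigs had a sibling lowered in both, against 22.7% and 29.2% for libraries 2 and 3, 30 of 109 contigs against 5 of 22 and 7 of 24 (one-sided Fisher's exact p = 0.511), numbers too few to decide. No biological explanation was tested.

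Call counts were set against splits of the libraries, only 10 for 3 against 3, too few for a share under 0.05. In S. superba 1 of 10 gave as many calls, the real one, for each of light in young leaves (2717 calls, highest other 74), light in mature leaves (436 and 10), age in full light (23426 and 19) and age in low light (19730 and 46). The same held for age in C. concinna, in full (1 of 10, 15032 and 3) and low light (1 of 10, 20044 and 0). For its light comparisons 2 of 10 splits gave as many in young leaves (16, highest other 53) and 2 of 10 in mature leaves (30, highest other 229). The splits with the highest other counts set full light replicate 1 and low light replicates 2 and 3 against the rest in young leaves, and full light replicate 1 and low light replicates 1 and 3 against the rest in mature leaves, which points to a structure of the samples other than light. For light by age, 2 of 100 splits drawn gave as many calls in S. superba (822, highest other 1315). The other was the mean light effect, young full with mature low light. In C. concinna 45 of 100 gave as many (3, highest other 33). Splits mixing the lights test for no light effect, not an equal one at both ages, so chance stays open.

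The mean effects of light and age correlated across unigenes with an r of -0.221 in C. concinna (jackknife SE 0.185) and 0.0312 in S. superba (SE 0.103), both within 2 SE of 0.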
